A study of Homo sapiens and Pan troglodytes and Pongo abelii with 55 samples.

How the data were processed

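The series holds RNA sequencing of pluripotent stem cells and of the cortical organoids grown from them in 4 primates. The human line was the embryonic stem cell line H9 and the rhesus macaque line was the embryonic stem cell line LYON-1; per the labels, both were kept on mouse feeder cells and lifted from them by hand before aggregation. The chimpanzee line Epi-8919-1A and the orangutan line Jos-3C1 were induced pluripotent stem cells, kept without feeders and aggregated in microwells at 10000 cells per aggregate. DKK1 (500 ng/mL), NOGGIN (500 ng/mL), SB431542 (10 uM) and cyclopamine (1 uM), which block WNT, BMP, Activin/Nodal and Hedgehog signalling, were given until day 18, and the medium held none of these factors from day 26. Chimpanzee and orangutan organoids also received bFGF and EGF at 10 ng/mL from day 18. According to the labels, the rhesus harvests for weeks 1 to 5 fell on day 6, day 11, day 17, day 22 and day 28. Species, stem cell type, line and culture method therefore varied together. Bulk library codes begin with fj in human and rhesus and, but for a library of orangutan week 1, with af in chimpanzee and orangutan. A library batch could thus coincide with these pairs of lines. The human and rhesus week 5 libraries carry codes outside the run of their line's other weeks, so a batch could coincide with week 5, the end point of changes and of the transient rule. A library of orangutan week 1 also carries a code of another series than that line's others. Of the 55 samples, 48 are bulk libraries, 2 for each of 24 combinations of line and week (weeks 0 to 5); the other 7 are human single-cell libraries, which were not analysed here. The bulk RNA was depleted of ribosomal RNA and sequenced with its strand kept.

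The submitters' processing notes name Bowtie2 2.2.1, STAR 2.5.1b, bedtools, DESeq2 1.14.1 and DESeq as used by the authors, together with Cufflinks 2.0.2, RSEM 1.3.0 and, for the single cells, Cell Ranger 2.0.0. They name the builds hg19 (GRCh37) and rheMac8 (Mmul_8.0.1); which tool made which value is not given in the sources used here. The main table, per the file headers, holds the authors' signal in normalized read counts (the base mean of their count model), 1 column per line and week, for 50063 genes after XIST, TSIX and chromosome Y genes were left out. Of these, 20153 are coding and 22122 are long noncoding RNA genes (lncRNAs); 30090 carry Ensembl and 19973 carry FANTOM identifiers, and current symbols were matched for 29177. The deposited gene tables in TPM, named by the authors for RSEM, cover hg19, panTro4, ponAbe2 and rheMac8, again with 1 value per week. Gene models in GTF form were used by class and coordinates alone, as other, unmeasured annotation; the authors' description says that they were FANTOM models projected from hg19 to the ape and macaque assemblies and filtered.

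Each deposited value is a mean over the libraries of a line and week, with no spread. Low values in the count table fell on 2 read-sized steps in 23 columns and on 3 in rhesus week 0, which explained 100% of them, so the columns behave as means of 2 scaled libraries or more. In the TPM table the chimpanzee values of weeks 1, 2, 3 and 5 fell on the steps that means of 3 libraries give (100%), although the labels list 2 and the count columns show 2 steps, so the 2 chimpanzee tables may not rest on the same libraries. A single read was worth between 0.216 and 1.77 normalized counts, and the larger step of a column was a median of 1.29 times the smaller (3.24 in rhesus week 3), a measure of unequal depth. Rhesus week 5 was given with enough decimals for both libraries to be solved for 35360 of 35360 values below 10000; 247 genes at or above 10000 were left out. The tests that had been planned on 2 against 2 libraries could not be run, because each group has 1 value. No per-sample column was left unused (0).

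Changes within a line were therefore called by size. A gene rose or fell between 2 weeks when log2((second + 1)/(first + 1)) was at least 1 or at most -1 and the higher mean was at least 50 normalized counts. A gene was measured in a line when a week reached 10. A gene was transient when a week between 1 and 4 passed that rule against both week 0 and week 5. A line differed from human when the 2 changes from week 0 to week 5 differed by at least 2 log2. A list was described per line by its median change and by that median's percentile among 10000 random lists matched on mean level in 20 bins; overlaps were set against 1000 draws matched on level. These rules have no p-value and measure no biological spread.

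A test across the 4 lines was added after the files' contents were known. It fitted line and week to 8 columns (4 lines at 2 weeks) with limma 3.58.1, with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05, for the 19357 genes measured in all 4 lines; n = 4 lines throughout. Its p-values measure spread between these lines, which are of 4 species. Lists with 3 or more tested members were tested with camera at its preset correlation of 0.01, and again with the correlation estimated. An adjusted p without another name comes from these fits. No count model (DESeq2 or edgeR) was run here, since the means are not counts of 1 library.

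Before the data were examined, 24 lists with 207 genes were fixed: pluripotency, neuroepithelium and radial glia, telencephalon and dorsal forebrain, intermediate progenitors, cortical neurons, Cajal-Retzius cells, ventral telencephalon and GABAergic cells, midbrain to spinal cord, eye field and retina, cortical hem and choroid plexus, mesoderm, endoderm, neural crest and surface ectoderm, fibroblast and feeder layer, glia, blood with microglia and endothelium, cell cycle, targets of WNT, BMP, Nodal/Activin and Hedgehog, glycolysis and hypoxia, endoplasmic reticulum stress, and known lncRNAs. Genes were named by rule: up to 4 members per list, the 5 largest rises and falls per line, 3 transient genes per human peak week and 3 in each other line, up to 10 lncRNAs transient in at least 3 lines, 3 genes each way per human weekly step and 5 each way per comparison with human, with a mean log2 level of at least 3. The rule ranked genes by smallest p; since no p exists within a line, the largest change was used. Further genes that share a list or a pattern, and LIN28A and COL3A1 in the plot of marker genes, were chosen after their values were seen. Single-gene results of a few genes are not reported here; the lists and counts include these genes.

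Tests on simulated data preceded use. Known changes were put into 200 of 50063 genes, all at 100 or more in human week 0. The size rule recovered 94% of 50 genes changed by 1.5 log2 and 100% at 2.0 log2 or more, with 2 false calls. The transient rule recovered 200 of 200 genes raised by 2 log2. Every gene got the same noise SD of 0.19, taken from the 2 rhesus week 5 libraries at 50 or more. The log2 ratio of these libraries had an SD of 0.49 at 50 to 200 and 0.27 at 1000 to 10000. The simulation therefore understates noise at low levels, and it took no spread from other lines or weeks. Of 50 unchanged lists, 2 lay outside the central 95% of random lists. The 4-line test recovered 8%, 50% and 100% of genes changed by 1, 2 and 4 log2, with 14 false calls (9.79% of the calls); 20 tables without change gave at most 1 call. Camera called the list that was raised and put 3 of 100 unchanged lists under 0.05. In both checks of lists, values were drawn for each gene on its own. These rates therefore say nothing of lists whose genes move together. Work was done in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9) and R 4.3.3.

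The scale of the values affects what can be read from them. Ribosome-depleted RNA keeps small structural RNAs, and in the TPM values the 5 largest genes held 86.2 to 94.4% of human, 51.4 to 65.2% of chimpanzee, 59.5 to 69.5% of orangutan and 82.0 to 89.6% of rhesus TPM (RN7SL1 held 34.7%, RN7SL2 23.3% and RMRP 21.2% at human week 0). Coding genes held 4.13 to 5.71, 23.8 to 37.3, 20.6 to 29.3 and 8.80 to 12.1% in the same order. Changes from week 0 to week 5 nevertheless correlated between the count and TPM tables at 0.88, 0.93, 0.92 and 0.86. The median change of the genes common to both was -0.03, -0.18, -0.19 and -0.01 in counts and 0.26, 0.58, 0.19 and 0.43 in TPM. The authors' scaling put the median change of all measured genes at 0.06, 0.02, -0.08 and 0.11; scaling within each line put it at -0.05, -0.06, -0.06 and -0.06. Projected gene models bear on comparisons between species, since a gene with a missing or shortened model in 1 assembly is listed near 0 there.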

Results

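RNA levels were followed weekly from pluripotent stem cells (week 0) to cortical organoids at week 5, in 1 line each of human, chimpanzee, orangutan and rhesus macaque. The labels list 2 bulk libraries for each of the 24 combinations of line and week, and the deposited table gives 1 mean for each. Every level below is that authors' mean in normalized read counts, without an SD or n of its own. Between 14901 (chimpanzee week 0) and 17560 (human week 5) genes reached 50 in a column. Both libraries could be solved in rhesus week 5. Their log2 ratio had an SD of 0.37 over genes at 50 or more, equal to an SD of 0.19 for a mean of 2 and 0.26 for a difference of such means. Between them 347 of 16469 genes differed by 1 log2 or more. The human and rhesus lines were embryonic stem cells from mouse feeders and the other 2 were feeder-free induced pluripotent cells. Species therefore cannot be told apart from stem cell type, culture or the series of library codes.

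The first comparison asked which genes changed from week 0 to week 5 in the 4 lines together. Pluripotency genes were among the largest falls. POU5F1, a core pluripotency factor, had a mean log2 change of -10.57 (SE 0.42, n = 4 lines, adjusted p = 0.000223), from 5070 to 3.73 in human and from 25700 to 22.2 in chimpanzee. PRDM14, a repressor of differentiation (-10.64, SE 0.41, adjusted p = 0.000223), VRTN (-10.94, SE 0.42, adjusted p = 0.000223) and MIR302CHG, host of the stem cell miR-302 cluster (-10.50, SE 0.49, adjusted p = 0.000293), fell in the same way. Among the largest rises were NSG2, a neuronal endosome protein (9.07, SE 0.50, adjusted p = 0.000374), GRIA2, a glutamate receptor subunit (8.63, SE 0.58, adjusted p = 0.000462), NEUROD6, a factor of young pyramidal neurons (8.54, SE 0.52, adjusted p = 0.000398), and TBR1, a factor of deep-layer and preplate neurons (8.14, SE 0.51, adjusted p = 0.000398). Other large rises were MAB21L1 (8.26), STMN4 (8.20), LRRTM2 (7.95), the lncRNA RP11-13J10.1 (7.82), the sodium channel SCN3A (7.68) and the glycine receptor subunit GLRA2 (7.62). L1TD1 (-9.03), EPHA1 (-8.87), CLDN6 (-8.87), ZFP42 (-8.35), ZSCAN10 (-8.23) and APELA (-8.13) were among the largest falls.

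Of 19357 genes measured in all 4 lines, 3491 rose and 3695 fell at adjusted p below 0.05 (limma, n = 4 lines), and 3138 and 2717 of these by at least 1 log2. Without the chimpanzee line the counts were 2283 and 2285, and with TPM rescaled to coding genes 1474 fell.

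**Figure D1:**
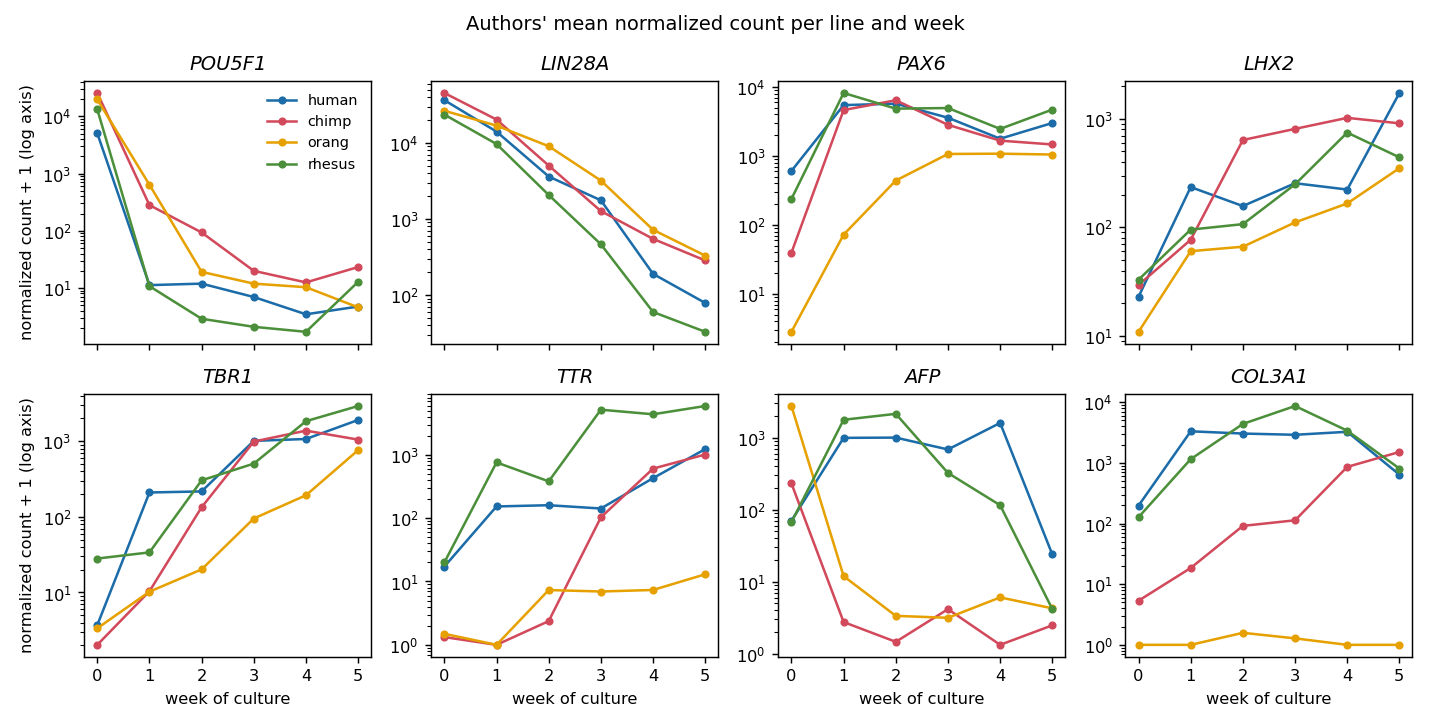
Authors' mean normalized count plus 1 (log axis) against week for POU5F1, LIN28A, PAX6, LHX2, TBR1, TTR, AFP and COL3A1 in the 4 lines; each point is 1 mean without error. POU5F1 fell from 13300 to 11.8 in rhesus while TBR1 rose from 27.1 to 2923.

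Most tested members of the lists of the cortical lineage rose. In the telencephalon and dorsal forebrain list, 9 of 12 members rose and 0 fell (median 4.79). The camera adjusted p = 4.07e-05 became adjusted p = 0.189 with an estimated correlation. Adjusted over the list alone 10 rose and 1 fell. DMRTA2 (adjusted p = 0.000454, from 4.72 to 770 in human), FEZF2, which specifies subcortical projection neurons (5.97), and LHX2, a cortical selector gene (4.99, adjusted p = 0.00089), were among them. Of 8 intermediate progenitor genes 7 rose (median 5.17, adjusted p = 0.000109; adjusted p = 0.189 with an estimated correlation). NEUROG2 (6.90) and NEUROD1 (6.36), both proneural factors, were examples. Of 12 cortical neuron genes 9 rose and 0 fell, and 10 rose adjusted over the list alone (median 5.68, adjusted p = 1.53e-06; adjusted p = 0.201 with an estimated correlation). Beside TBR1 and NEUROD6 these included STMN2 (6.60) and DCX, a microtubule protein of migrating neurons (5.62). SLC17A7 (-0.61, adjusted p = 0.586), RBFOX3 (0.67, adjusted p = 0.512) and BCL11B (1.61, adjusted p = 0.0678) were not called over all genes. Of 7 Cajal-Retzius genes 5 rose (6 adjusted over the list alone; median 4.66, adjusted p = 0.000397; adjusted p = 0.189 with an estimated correlation). RELN, the secreted guide of cortical layering, had a mean change of 6.26 (adjusted p = 0.000727) and reached 39758 in rhesus and 1940 in orangutan. EBF3 had 6.19.

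Of 11 neuroepithelial and radial glial genes 7 rose and 1 fell (median 2.47, adjusted p = 0.00625; adjusted p = 0.325 with an estimated correlation). PAX6, a factor of cortical progenitors (5.09, adjusted p = 0.00599), SOX1 (4.63, adjusted p = 0.0179), FABP7, a fatty acid binding protein of radial glia (4.31, adjusted p = 0.000575), and DACH1 (4.10) rose, and PROM1 fell (-2.48, adjusted p = 0.00390). HES5, a Notch target, rose by size in human (12.5 to 1690), chimpanzee (8.63 to 1870) and rhesus (15.2 to 180.4) and was listed at 0 in orangutan at every week. All 9 cell cycle genes fell (median -1.88, adjusted p = 0.000105; adjusted p = 0.362 with an estimated correlation), among them BUB1 (-2.44, adjusted p = 0.00305) and MKI67 (-1.46, adjusted p = 0.0272). All 10 tested pluripotency genes fell (median -8.21, adjusted p = 7.3e-09; adjusted p = 0.187 with an estimated correlation). With an estimated correlation none of these lists was called. The estimates ran from -0.046 (Cajal-Retzius) to 0.92 (cell cycle). Since the Cajal-Retzius estimate lies below the preset 0.01, the lost calls cannot be put down to correlation between genes alone.

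**Figure D2:**
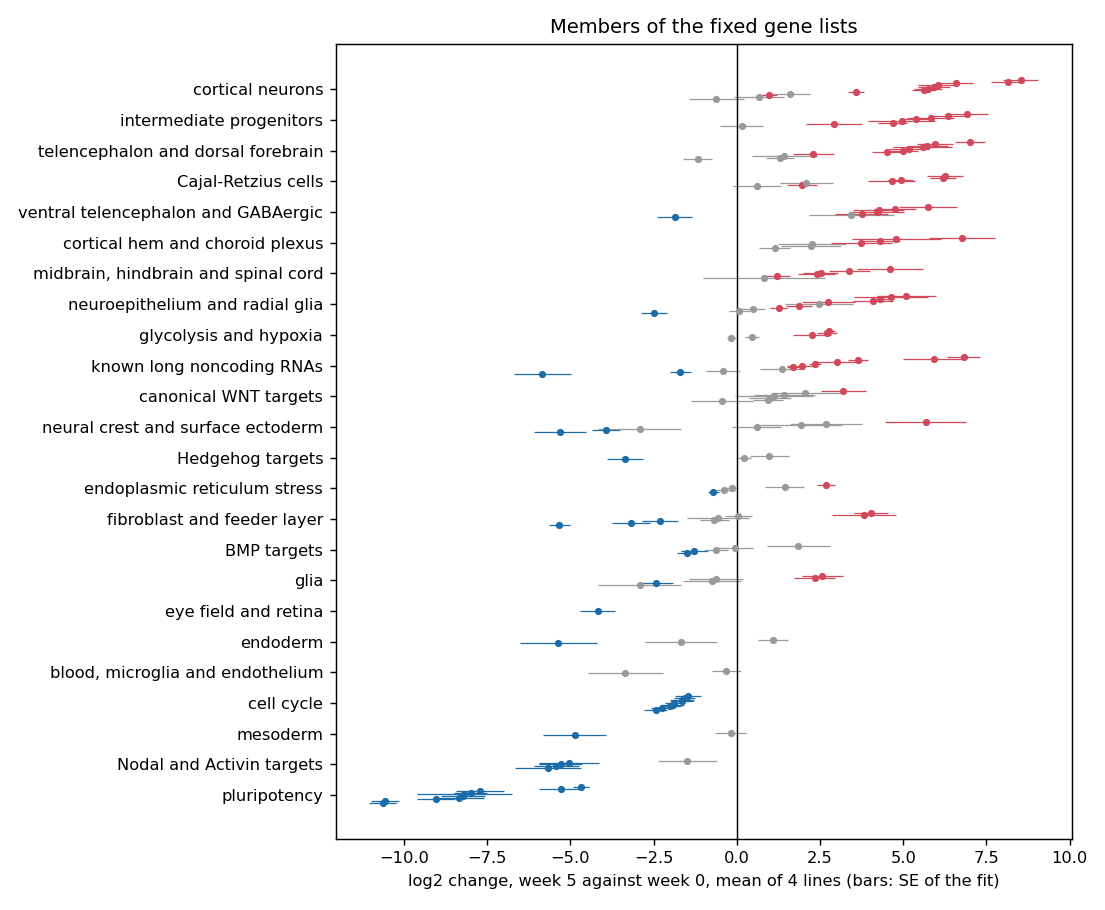
Mean log2 change from week 0 to week 5 over the 4 lines for members of the lists, with bars of 1 SE of the fit (n = 4 lines); red members rose and blue members fell at adjusted p below 0.05, grey members were not called. Pluripotency genes lie at the bottom (median -8.21), cortical neuron genes at the top (median 5.68).

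Markers of regions outside the dorsal forebrain were examined in the same way. Of 7 ventral telencephalic and GABAergic genes 5 rose and 1 fell (6 rose and 1 fell adjusted over the list alone; adjusted p = 0.0109; adjusted p = 0.300 with an estimated correlation). GAD2, which makes GABA (5.75, adjusted p = 0.00369), ended at 1100 in human and 991 in rhesus but at 91.6 in chimpanzee and 41.7 in orangutan. DLX1 had 4.76 and LHX6, a factor of cortical interneurons, fell (-1.87, adjusted p = 0.0321). Within lines the median of this list was 6.11 in human, above every random list but with a median of 2.39 at the step from week 4 to 5 alone, whose libraries carry codes outside the line's run, 4.57 in rhesus, 3.498 in orangutan and 1.499 in chimpanzee (percentile 91.0). Of 7 midbrain, hindbrain and spinal cord genes 6 rose (median 2.52, adjusted p = 0.00464; adjusted p = 0.201 with an estimated correlation), including HOXA5 (4.61, adjusted p = 0.0120), which reached 478 in human and 36.0 in orangutan. EN1, the midbrain-hindbrain factor, was not called (0.82, adjusted p = 0.745). Of 7 cortical hem and choroid plexus genes 4 rose (median 3.74, adjusted p = 0.00539; adjusted p = 0.362 with an estimated correlation, and 0.0518 by the rotation test fry). TTR, the choroid plexus thyroid hormone carrier (6.77, adjusted p = 0.00331), rose to 1230 in human, 1010 in chimpanzee and 5891 in rhesus (3207 and 8576 in the pair of libraries) and stood at 12 in orangutan. LMX1A (4.79), RSPO2 (4.30) and WNT8B (3.74) rose with it. The eye field and retina list had 2 tested members, too few for a set test, of which 0 rose and PMEL, a melanosome protein also high in stem cells, fell (-4.18, adjusted p = 0.00196). In human by itself 4 of its 7 measured members rose (median 2.91, percentile 99.78). Their median was 2.60 at the step from week 4 to 5 alone, whose libraries carry codes outside the line's run. SIX6 went from 6.04 to 70.8, but with week 4 in place of week 5 its change was -2.82.

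Markers of other cell types followed. The endoderm list had 3 tested genes, with 0 risen and 1 fallen (adjusted p = 0.664): AFP, a fetal liver and yolk sac protein, had -5.36 (adjusted p = 0.0124). In rhesus 5 of its 7 members fell by size, SOX17 from 160 to 2.18 and GATA4 from 134 to 2.06. Of the 2 tested mesoderm genes, too few for a set test, KDR, the VEGF receptor, fell (-4.87, adjusted p = 0.00851). Of 7 neural crest and surface ectoderm genes TFAP2B rose (5.67, adjusted p = 0.0118) and the epithelial keratins KRT18 (-5.31, adjusted p = 0.00326) and KRT8 (-3.92) fell. As a set they were not called (adjusted p = 0.809; the median of 0.59 and the mean of -0.18 differ in sign). Of 8 fibroblast and feeder layer genes DCN (4.04) and LUM (3.83), matrix proteoglycans, rose (set adjusted p = 0.450). TAGLN, an actin-binding protein (-5.34, adjusted p = 0.000398), COL1A1 (-3.18, adjusted p = 0.00708) and THY1 (-2.32) fell. In chimpanzee COL1A1 fell from 363 to 164 but changed by 0.03 with week 4 in place of week 5. Of 6 glial genes S100B (2.34) and OLIG2 (2.57) rose and AQP4 fell (-2.42, adjusted p = 0.0118). The glial set was not called (camera adjusted p = 0.921). Neither of 2 tested blood, microglia and endothelium genes was called (1 fell adjusted over the list alone), and no set test was run on them; CDH5, an endothelial cadherin, fell from 90.4 to 0.305 in orangutan and from 69.7 to 0 in rhesus.

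Among pathway lists, Nodal and Activin targets fell: 4 of 6 fell and 0 rose (median -5.17, adjusted p = 0.00625; adjusted p = 0.201 with an estimated correlation). NODAL (-5.43, adjusted p = 0.00193) and its antagonist LEFTY2 (-5.68) were examples. In the glycolysis and hypoxia list 3 of 5 rose (median 2.25, adjusted p = 0.0218; adjusted p = 0.201 with an estimated correlation). These were VEGFA, an angiogenic factor (2.78, adjusted p = 0.000398), DDIT4 (2.71) and BNIP3 (2.25), which respond to low oxygen. ALDOA, a glycolytic enzyme, stood at 4240 and 3550 in human. DDIT3, a stress-induced factor, rose (2.68, adjusted p = 0.00114) and the chaperone HSPA5 fell (-0.70, adjusted p = 0.0211) in the list of 5 endoplasmic reticulum stress genes (adjusted p = 0.829; median -0.14, mean 0.57). Of 7 WNT targets LEF1 rose (3.21, adjusted p = 0.0111), and the set was not called (adjusted p = 0.158). Its median was -1.26 in human (percentile 0.54) and 3.53 in chimpanzee (99.99), 3.19 in orangutan (99.98) and 1.36 in rhesus (98.4). SP5 fell from 876 to 64.6 in human and stood at 2.66 and 41.2 in chimpanzee. ID1 (-1.50) and SMAD7 (-1.28) fell among 5 BMP targets (adjusted p = 0.411). GLI1, a direct Hedgehog target, fell (-3.36, adjusted p = 0.0045) among 4 (adjusted p = 0.931; median 0.28, mean -0.45). Of 11 known lncRNAs 7 rose and 2 fell (median 1.95, adjusted p = 0.0109; adjusted p = 0.201 with an estimated correlation). LINC00461 (6.82, adjusted p = 0.000576), DLX6-AS1 (5.92), SOX2-OT (3.64) and MIAT (2.35) rose. LNCPRESS1, a stem cell lncRNA (-5.84, adjusted p = 0.0032), and DANCR (-1.70) fell.

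The same weeks were then compared within each line by size, to ask what each line changed. In human 4346 genes rose and 3782 fell. Of the largest rises, NSG2 went from 1.38 to 4310 (10.82), MYT1L, a neuronal zinc finger factor, from 1.97 to 3800 (10.32) and GRIA2 from 12.5 to 13800 (10.00). HOXD3, a gene of the posterior axis, went from 1.28 to 2210 (9.92) and NEUROD6 from 0 to 898 (9.81). The lncRNA RP11-431J24.2 went from 6210 to 0.622 (-11.90), PRDM14 from 2840 to 0.622 (-10.77) and the lncRNA RP5-865N13.2 from 2160 to 0.622 (-10.38). APELA, a peptide hormone of stem cells, went from 1770 to 0.622 (-10.09) and VRTN from 1760 to 0.622 (-10.08). In chimpanzee 3745 rose and 4627 fell. TTR went from 0.326 to 1010 (9.57), POU3F3, an upper-layer factor, from 4.23 to 3270 (9.29) and STMN4 from 2.06 to 1740 (9.15). MAB21L1 and TBR1 each went from 1.03 to 1050 (9.02). NANOG, a core pluripotency factor, went from 4230 to 0.217 (-11.76) and VRTN from 3430 to 0.408 (-11.25). EPHA1 went from 7680 to 2.77 (-10.99), L1TD1 from 21800 to 11.3 (-10.79) and ZFP42 from 3850 to 1.52 (-10.58).

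In orangutan 3329 genes rose and 4215 fell. LRRTM2, a synapse organizer, went from 1.37 to 2130 (9.81), RP11-13J10.1 from 0.342 to 1200 (9.81) and MAB21L1 from 1.83 to 2450 (9.76). GRIA2 went from 4.03 to 4170 (9.70) and NTRK2, the BDNF receptor, from 5.55 to 5030 (9.59). TDGF1, a Nodal co-receptor, went from 11900 to 0.588 (-12.87) and POU5F1 from 19800 to 3.58 (-12.08). MIR302CHG went from 3040 to 0 (-11.57), CLDN6 from 6230 to 1.19 (-11.47) and VRTN from 5300 to 0.892 (-11.45). In rhesus 4385 rose and 3744 fell. OPRM1, the mu opioid receptor, went from 6.52 to 7080 (9.88) and ACTL6B, a neuronal chromatin remodelling subunit, from 0.42 to 857.6 (9.24). GLRA2 went from 2.57 to 1278 (8.49), NSG2 from 17.1 to 6207 (8.42) and the glycine transporter SLC6A5 from 1.3 to 762.2 (8.37). DPPA4 went from 7480 to 3.21 (-10.79), PRDM14 from 2700 to 1.03 (-10.38) and POU5F1 from 13300 to 11.8 (-10.02). IFITM1 (3070 to 1.09, -10.52) and IFITM2 (3000 to 1.09, -10.49) are close paralogs, so which of them was read is uncertain.

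The higher share of the changed genes was 53.5% in human, 44.7% in chimpanzee, 44.1% in orangutan and 53.9% in rhesus; with TPM rescaled to coding genes it was 67.8, 75.4, 60.2 and 73.8%, and with TPM scaled by median ratio 49.5, 22.5, 40.6 and 48.1%. The balance of rises and falls thus depended on scaling, while the 5 largest rises and falls of each line moved by 8 log2 or more. Among lncRNAs 938 rose and 884 fell in human, 1062 and 346 in chimpanzee, 719 and 436 in orangutan, 964 and 430 in rhesus.

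To see when the changes took place, each week was compared with the one before. The step from week 0 to 1 was the largest in every line, with 3927 genes in human, 5986 in chimpanzee, 5236 in orangutan and 4244 in rhesus. In human HES5 (12.5 to 1360), HOXD3 and ELAVL4, an RNA-binding protein of neurons (2.75 to 392), rose. RP11-568A7.2 (3490 to 4.78), POU5F1 (5070 to 10.2) and PRDM14 (2840 to 6.44) fell. Later human steps moved 1384, 801, 630 and 1565 genes. At week 2 RP11-128I7.1 (0.73 to 133), CLRN1 (11.6 to 373) and SLC6A5 (57.9 to 1100) rose. AC003003.5 (346 to 14.2), NOS2 (955 to 63.7) and KCNJ13 (131 to 8.37) fell. At week 3 DLX6-AS1 (16.9 to 439), NEUROD6 (48.6 to 638) and SLA (9.04 to 126) rose. RP11-128I7.1 (133 to 0.642), APELA (52.8 to 2.57) and ALDH1A3, a retinoic acid enzyme (83.9 to 4.66), fell. At week 4 the neuropeptide gene TAC3 (5.91 to 76.3), KCNJ13 (9.19 to 92.2) and CTD-2009A10.1 (17.7 to 114) rose. AP000705.7 (60.1 to 1.44), SOX10, a neural crest factor (51.9 to 2.18), and DBX2 (94.0 to 5.65) fell.

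From week 4 to 5 the human organoids changed 1565 genes (1093 rose, 472 fell) against 562 in chimpanzee, 328 in orangutan and 644 in rhesus. The replication histone gene HIST1H3C (6.67 to 919), MIR205HG (1.01 to 201) and VAX1, a ventral forebrain factor (1.44 to 202), rose. SI, an intestinal disaccharidase (80.2 to 0), AFP (1600 to 22.8) and SERPINA1, a liver protease inhibitor (130 to 1.24), fell. Of 23 lists set against random lists at this step, a comparison chosen after the data were seen, the medians of 6 lay above the central 95% of the random lists and those of 5 below it. In the ventral telencephalic list 5 of 9 measured members rose and 0 fell (median 2.39; DLX1 from 15.1 to 510, DLX5 from 6.71 to 204), in the eye field list 3 of 7 and 0 (median 2.60; RAX from 2.18 to 171) and in the telencephalon list 9 of 12 and 0 (median 1.53). The neural crest, cortical neuron and Hedgehog lists were the others above. The endoderm list (median -3.03), the fibroblast list (-0.73) and those of pluripotency, midbrain to spinal cord and hem lay below. In the cell cycle list 0 of 9 measured members rose and 0 fell (median -0.21, percentile 45.6), so HIST1H3C did not rise with them. Changes of all genes at this step correlated at -0.02 with chimpanzee, 0.02 with orangutan and 0.14 with rhesus.

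Over all weeks 11748 human genes (58.9% of those that reached 50), 11937 in chimpanzee (66.4%), 10698 in orangutan (59.9%) and 11690 in rhesus (63.1%) changed by size between some pair of weeks. In chimpanzee the successive steps moved 1940, 1195, 783 and 562 genes after the first, in orangutan 1923, 1172, 762 and 328, and in rhesus 1583, 1624, 2271 and 644. By the test across the 4 lines (limma, n = 4 lines) 5008 genes changed from week 0 to 1 (2157 rose, 2851 fell), 546 from week 1 to 2, 1 from week 2 to 3, 55 from week 3 to 4 and 0 from week 4 to 5. At that last step 1485 had an unadjusted p below 0.05. With a line left out these counts ranged over 1008 to 3289, 0 to 421, 0 to 195, 0 to 462 and 0. Without chimpanzee 1008 genes changed at the first step, and without human, chimpanzee or rhesus 0 at the step from week 1 to 2. By contrast 195 without rhesus and 462 without chimpanzee changed at the next steps.

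**Figure D3:**
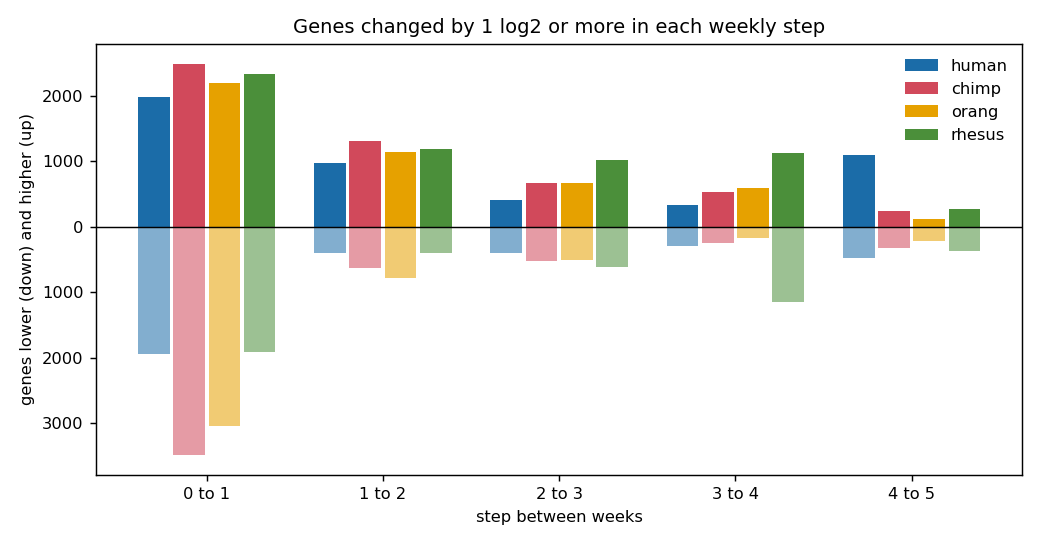
Number of genes that rose (bars up) or fell (paler bars down) by at least 1 log2 at a mean of 50 or more, for each weekly step in each line; bars are single counts without error. The step from week 0 to 1 is the largest in each line (3927 in human), and the human step from week 4 to 5 (1565) exceeds its previous one (630).

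Genes at least 1 log2 higher in a week from 1 to 4 than at weeks 0 and 5, here called transient whatever their level at both ends, were counted next. Of them 930 were transient in human, 903 in chimpanzee, 924 in orangutan and 1267 in rhesus, that is 4.66, 5.03, 5.17 and 6.83% of genes that reached 50. Human peaks fell in week 1 for 222, week 2 for 439, week 3 for 106 and week 4 for 163. In rhesus they fell in these weeks for 323, 384, 505 and 55; week 3 of rhesus had the most unequal libraries (3.24 times), and without it 916 rhesus genes were transient. DBX2, a homeobox gene of the intermediate neural tube, peaked in week 2 in all 4 lines, at 680 in human (2.65 at week 0, 8.09 at week 5), 173 in chimpanzee, 385 in orangutan and 388 in rhesus. HEYL, a Notch target, peaked then at 396, 705, 363 and 371. FBN1, the microfibril protein fibrillin (3520, 3520, 1760 and 5100), LIX1 (2320, 3980, 4370 and 2660) and the protease PRSS23 (3300, 9630, 3590 and 4440) peaked in week 1 in all 4. PTCH1, the Hedgehog receptor, peaked at 4050, 3050, 2190 and 5150. SOX10 was transient in each line (691, 434, 1190 and 375), as were WNT2B (3010, 683, 568 and 3660), COL2A1 (2650, 5960, 3520 and 6010) and IRX3 (769, 1270, 2300 and 693).

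The 66 genes that were transient in all 4 lines (54 coding, 11 lncRNAs) exceeded the 0.047 of independent lines; 1000 draws matched on level gave a mean of 0.127 and at most 2. Human shared 203 transient genes with chimpanzee (highest draw 54), 177 with orangutan (51) and 303 with rhesus (71). Chimpanzee and orangutan shared 294 (56), chimpanzee and rhesus 243 (70), orangutan and rhesus 222 (72). The peak fell in the same week for 59.6% of the human and chimpanzee genes (42.6% for independent peaks), 33.9% with orangutan (31.4%) and 45.5% with rhesus (32.6%). It did so for 56.5% of the chimpanzee and orangutan genes (38.8%), 32.9% of the chimpanzee and rhesus genes (28.8%) and 26.6% of the orangutan and rhesus genes, below the 31.4% of independent peaks. When the peak was set against its 2 neighbouring weeks in place of weeks 0 and 5, 254 human genes passed. Against weeks 0 and 5 but with a level of 200 or more, 523 did.

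The transient genes with the largest folds in each line are given next; DBX2, MTTP and CDH19 among those of human were transient in all 4 lines. In human APOA4, an apolipoprotein (2.75, 165 at week 1, 0 at week 5), CDH19, a cadherin of glial precursors (3.93, 186, 0), and FGG, fibrinogen gamma (2.7, 315, 7.34), led week 1. DBX2, LINC02306 (25.6, 1410, 15.6) and MTTP, which loads lipoproteins (33.3, 1600, 42.6), led week 2. AC005863.1 (4.08, 263, 6.55), CARTPT (1.28, 79.2, 1.41) and ARHGAP36 (11.4, 189, 11.7) led week 3. TLX1 (0, 180, 2.49), SI (0.639, 80.2, 0) and OR51E2 (0, 61.4, 0.622) led week 4. In chimpanzee RP11-459O1.2 (2.17, 397, 3.73), the interneuron peptide SST (0.326, 743, 10.0) and CTXND1 (4.5, 426, 6.04) peaked in week 2. In orangutan HPSE2 peaked in week 1 (1.86, 430, 0.588), UBD (14, 1370, 9.04) and WNT3A, a cortical hem WNT (3.04, 1100, 11.5), in week 2. In rhesus the liver proteins SERPINA1 (1.21, 769, 0) and FGB (2.14, 581, 0) peaked in week 1 and OGN, a matrix proteoglycan (0, 1490, 8.54), in week 3.

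**Figure D4:**
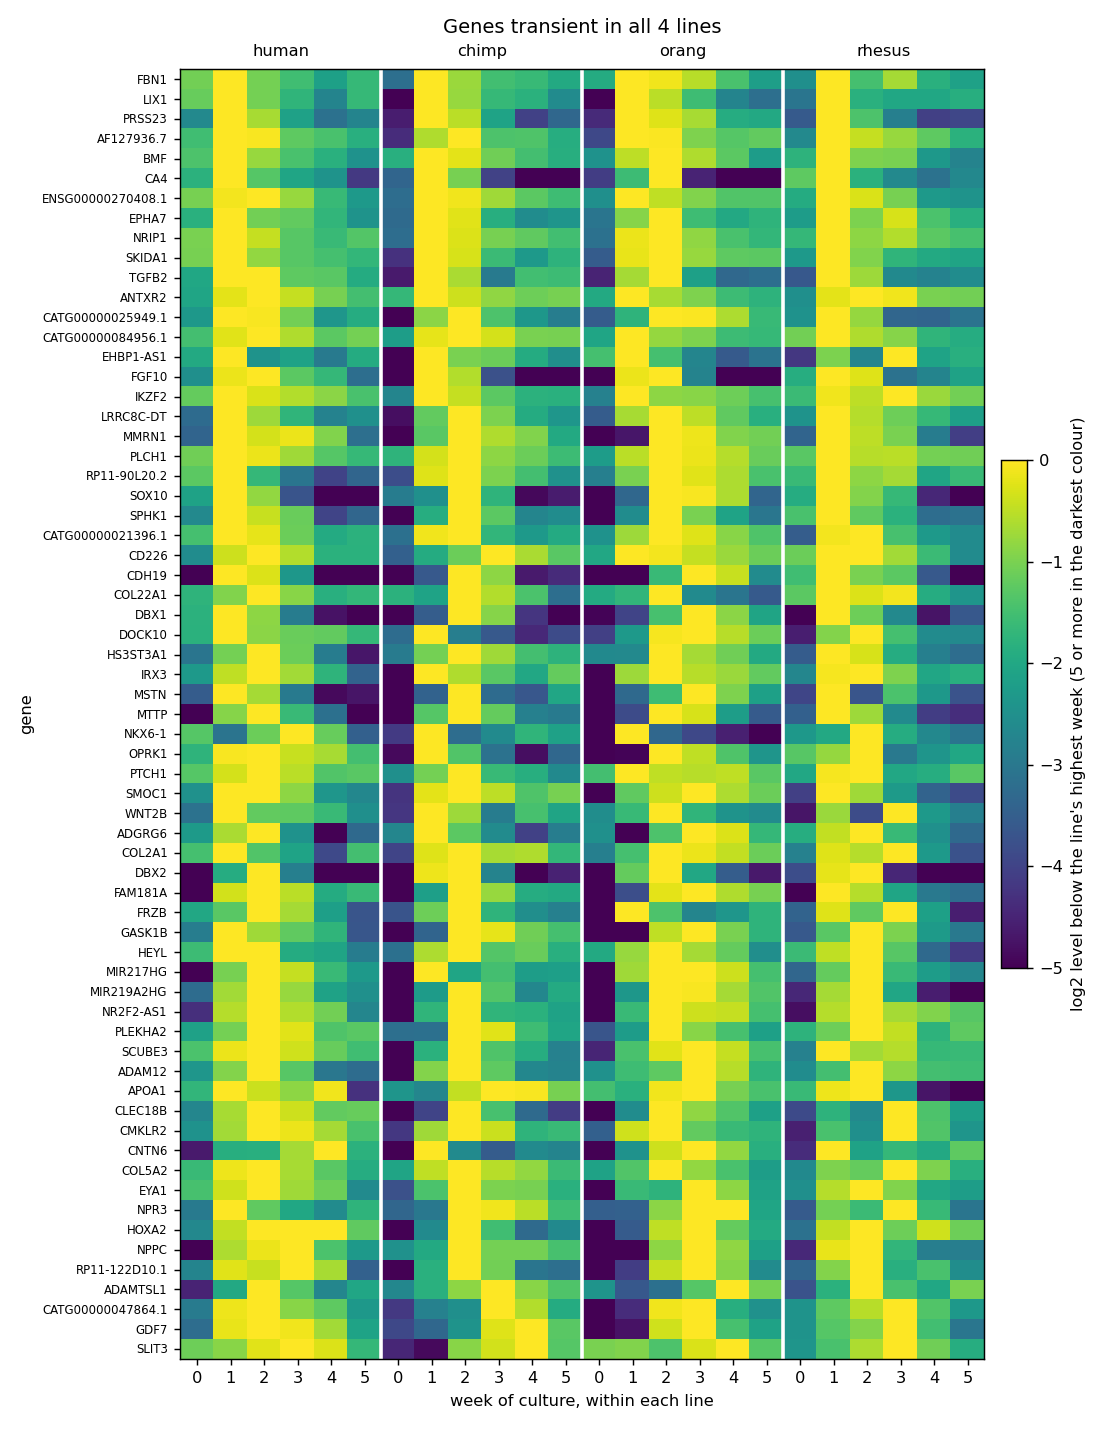
Heat map of genes transient in all 4 lines; rows are genes, columns weeks 0 to 5 within each line, and colour is log2 below the line's highest week of the authors' mean normalized count plus 1, without error. DBX2 stood at 680 in human week 2 against 2.65 at week 0 and 8.09 at week 5.

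Transient lncRNAs were examined for the same question. In 3 or 4 lines 37 lncRNAs were transient and in all 4 lines 11 were. MIR219A2HG, host of a microRNA gene (chromosome 9, 131151540 to 131155780, minus strand of hg19), peaked in week 2 at 2790, 1950, 2800 and 3050 in human, chimpanzee, orangutan and rhesus; it lies opposite COQ4 and URM1. NR2F2-AS1 (chromosome 15, 96623846 to 96873578, minus strand) peaked in week 2 at 15200, 4330, 1020 and 13700 and lies opposite NR2F2. MIR217HG (chromosome 2, 56181588 to 56276803) and AF127936.7 (chromosome 21, 16189175 to 16291039) overlap no coding gene and peaked at 706 and 668 in human. EHBP1-AS1 (chromosome 2, 63270554 to 63277727) is opposite EHBP1 and OTX1, LRRC8C-DT (chromosome 1, 90048800 to 90099024) opposite LRRC8B and LRRC8C, and RP11-90L20.2 (chromosome 1, 201691186 to 201708929) opposite NAV1. CATG00000047864.1 (chromosome 2, 20860897 to 20866637) is an unspliced model in hg19, as are RP11-90L20.2 and CATG00000025949.1. RP11-122D10.1 (chromosome 15, 37168561 to 37179249) shares strand and position with MEIS2, and CATG00000025949.1 (chromosome 15, 93629022 to 93630692) lies in an intron of RGMA on its strand, so reads of the coding genes could not be told apart from theirs.

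A larger share of lncRNAs than of coding genes was transient: 303 of 3840 against 529 of 14488 in human (7.89 and 3.65%) and 188 of 2682 against 663 of 13865 in chimpanzee (7.01 and 4.78%). The shares were 216 of 2576 against 654 of 13985 in orangutan (8.39 and 4.68%) and 334 of 2973 against 826 of 14130 in rhesus (11.2 and 5.85%). lncRNAs had lower levels, and coding genes matched to them on level were transient at 6.51, 9.74, 9.60 and 13.3%. The ratio of the shares went from 2.16, 1.47, 1.79 and 1.92 to 1.21, 0.72, 0.87 and 0.84 with matching, and at a minimum of 2 log2 the matched human ratio was 0.97. Within quartiles of level the ratio was above 1 in 4 quartiles in human, 3 in rhesus, 2 in orangutan and 1 in chimpanzee, and the highest quartile held 201, 88, 76 and 117 lncRNAs. The excess over coding genes thus depended on how level was controlled. No test was possible within a line.

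The last comparison asked which genes changed differently from human between week 0 and week 5. In chimpanzee 1363 of 17048 genes changed by at least 2 log2 more than in human and 1200 by at least 2 log2 less; in orangutan 954 and 1426 of 17099, in rhesus 895 and 788 of 17061. MYBPC1, a myosin-binding protein, stood at 0.705 and 21.2 in chimpanzee against 119 and 1.24 in human (difference 9.45). LGI1, a secreted synaptic protein, stood at 14.9 and 1320 against 606 and 119 (8.71). PAX3, a dorsal neural tube and crest factor, stood at 5.97 and 1960 against 1170 and 857 (8.58). EN1 (8.66) and LINC01956 were also higher. SPTSSB (2200 and 5.47 against 19.5 and 31.7, -9.08), SLA (20.8 and 7.43 against 0.639 and 235, -8.54) and TLE2 (285 and 16.0 against 5.94 and 118, -8.17) were lower. ZDHHC22 (2290 and 42.9 against 68.3 and 327, -7.95) and AP1M2 (4220 and 2.72 against 103 and 16.6, -7.58) were lower.

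In orangutan EN1 (0.685 and 199 against 45.8 and 0.622, 11.74), MYBPC1 (3.54 and 286, 11.73) and LINC01956 (1.52 and 115, 11.13) were higher. SLFN13 (2.02 and 128 against 602 and 12.2, 10.93) and GREB1L (17.9 and 2800 against 8270 and 1170, 10.03) were higher as well. AC061961.2 (1330 and 25.4 against 2.65 and 60.1, -9.72), TLE2 (-8.13) and SUSD4 (4700 and 271 against 28.4 and 451, -8.05) were lower, as were SIM1, a hypothalamic factor (91.7 and 11.7 against 10.4 and 345, -7.79), and the serotonin receptor HTR7 (5270 and 12.6 against 83.0 and 46.8, -7.78). In rhesus RP11-354K4.2 (13.3 and 19.1 against 725 and 2.03, 8.39), MICB (4.33 and 28.5 against 219 and 2.82, 8.31), the chloride channel CFTR (12.6 and 406 against 86.1 and 8.75, 8.06), SLFN13 (7.98) and SHISA3 (0.42 and 6.49 against 405 and 9.54, 7.67) were higher. MMEL1 (60.8 and 0 against 6.63 and 59.0, -8.92), VAX1 (21.1 and 3.15 against 4.72 and 202, -7.56) and TRIM4 (585 and 326 against 4.03 and 422, -7.23) were lower, as were the paralogs IFITM2 (-7.81) and IFITM1 (-7.18). The human rise of VAX1 came at the step from week 4 to 5, whose libraries carry codes outside the line's run.

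Genes called in both lines of a pair mostly moved the same way. With chimpanzee 1692 genes rose and 1646 fell in both (593 and 619 if independent) and 289 moved in opposite directions; with orangutan 1662, 1550 and 270; with rhesus 2231, 1822 and 136. Across 17762 genes the changes correlated at 0.65 for human with chimpanzee, 0.65 with orangutan and 0.75 with rhesus, 0.80 for chimpanzee with orangutan, 0.67 for chimpanzee with rhesus and 0.68 for orangutan with rhesus. The line pairs with the higher correlations, human with rhesus and chimpanzee with orangutan, are the pairs that shared stem cell type, culture and series of library codes. A limma interaction between these pairs and week called 0 genes at adjusted p below 0.05 (n = 4 lines), with 2817 at unadjusted p below 0.05 against 407 and 498 for the other two ways of pairing the lines.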

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

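The counts of loci, the search for genes that moved in opposite directions and the tests in this part were chosen after the data were seen.

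Transcripts assembled by the authors outside the reference gene set were not analysed here beyond a count. Such loci reached a TPM of 1 or more in at least 1 week for 41 of 4892 loci in human, 1112 of 9579 in chimpanzee, 2899 of 23271 in orangutan and 310 of 7175 in rhesus.

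From week 0 to week 5, 25 genes fell in human and rhesus and rose in chimpanzee and orangutan by at least 1 log2 in each line, among them EN1 (-4.85, 3.81, 6.89 and -2.57 in human, chimpanzee, orangutan and rhesus), MYBPC1, ANGPT1, PRRX1, BMP5 and ACTA2. Another 24 genes moved the other way round, among them FAM163A (1.53, -4.57, -4.73 and 3.56), TRPC7, S100A14, ALDH1L1 and KCNJ6. Such genes were not counted for the other ways of pairing the lines, so these counts have no reference. No level was required beyond being measured in every line. The interaction of week with these pairs of lines was tested with limma (n = 4 lines) and 0 genes passed; the smallest adjusted p = 0.0528 was that of ANGPT1, a ligand of endothelial receptors (difference 6.33). The pairs differ in stem cell type, feeder cells, aggregation, bFGF and EGF in the medium, species and series of library codes. These causes cannot be told apart and were not tested.

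The changes shared by the 4 lines were set against all 32 estimable splits of the 8 columns into 4 and 4. From week 0 to 5 the real grouping gave 7186 genes and the highest other 0, and 1 split was as large (the real one). In the other splits a change between the weeks goes into the residual spread, which makes calls less likely. The size of the gap between 7186 and 0 therefore does not measure how strong the shared change is. The real grouping was also the largest from week 0 to 1 (5008 against 0; 1 split), week 1 to 2 (546 against 14; 1 split), week 2 to 3 (1 against 0; 1 split) and week 3 to 4 (55 against 1; 1 split). From week 4 to 5 the real grouping gave 0 and the highest other 3, and since every count is at least 0, all 32 splits were as large by construction and the splits say nothing there. Only 8 of the splits part the 2 weeks of every line, and 1 of these (the real one) was as large at the other steps, which is the smallest share that 4 lines allow; the single gene from week 2 to 3 carries little weight.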

How the results depend on the processing

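A pseudocount of 0.1, median-ratio scaling of the count table, runs without a filter, a minimum of 2 log2 for transient genes, neighbouring weeks, peaks within 1 week, quartiles of level, genes measured in a pair of lines, week 4 as the end of the comparisons with human, the estimated correlation and fry were fixed before the data were examined. The other levels and minimums, TPM, matching on level, week 4 in the other results, lines left out and the tests across lines themselves were chosen after the data were seen. No paired analysis was possible because, among libraries, each line and week is given as 1 mean and the numbers of the libraries name no pair; the tests across lines fit line beside week. Tests with count models on 2 against 2 libraries, TMM and RLE scaling, fits without a trend within a line and leaving out single libraries were not run, for the same reason. Of 300 counts and ratios under other settings 167 stayed within 1.5 times and of 42 set tests 28 gave the same call. Of 120 counts of single weekly steps 52 stayed within 1.5 times; of 1531 changes of single genes 771 stayed, 749 moved in size and 11 reversed. Values are given for human, chimpanzee, orangutan and rhesus in this order, and the cause of a shift was not tested.

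With a level of at least 10 instead of 50, genes that rose numbered 7144, 6476, 5618 and 7015, genes changed between any weeks 18965, 18386, 16628 and 18594, step sums (8307, 10466, 9421 and 10366 before) 16929, 18060, 16219 and 19785, and transient genes 1874, 1669, 1596 and 2546. With a level of 200 these were 2756, 2148, 2082 and 2850 risen, 7615 changed in human, sums of 4316, 6295, 5577 and 5753, and 523, 541, 552 and 666 transient. Without a filter 11452, 9824, 9000 and 12173 rose, 8173, 8902, 8055 and 7441 fell, 32322, 30945, 27502 and 31795 changed, the step sums were 39820, 32251, 28827 and 43369, and 4612, 2737, 2781 and 5522 were transient; 2430 genes fell in the 4 lines together, and 3727 and 4157 (chimpanzee), 3199 and 4479 (orangutan) and 3619 and 3180 (rhesus) genes differed from human.

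With a minimum of 2 log2, 2135, 1895, 1645 and 2386 rose, 1333, 1620, 1719 and 1529 fell and 269, 229, 295 and 432 were transient, with overlaps of 52 (human and chimpanzee), 34 (human and orangutan), 69 (human and rhesus), 67 (chimpanzee and orangutan), 42 (chimpanzee and rhesus) and 49 (orangutan and rhesus). A peak above both neighbouring weeks was found for 254, 391, 354 and 597. Peaks within 1 week of each other were shared by 186, 148, 272, 270, 216 and 173 genes in the order of these pairs. A difference of 1 log2 from human was passed by 3316 and 3722 genes in chimpanzee, 2743 and 3653 in orangutan and 2573 and 2598 in rhesus; with week 4 as the end 525 were lower in rhesus.

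With TPM rescaled to coding genes 1993, 1522, 2305 and 1787 fell, 1474 fell in the 4 lines together, the chimpanzee steps summed to 6448 and 1675 human genes were transient; COL1A1 (0.25) and SOX10 (0.87) in chimpanzee, KDR in human (0.00616) and LGR5 (0.0259) and MIXL1 (0.0612) in rhesus changed sign. TPM scaled by median ratio gave 1793 risen in chimpanzee. The fit to all 24 columns called 5803 risen and 5936 fallen. With week 4 in place of week 5 COL1A1 in chimpanzee (0.0314) and APOA1 (1.60), ID2 (0.13), LDHA (0.15), SIX6 (-2.82) and TP63 (-1.60) in human changed sign.

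With a line left out, the genes that rose ranged over 2283 to 2733 and those that fell over 2285 to 3271, and the weekly steps over 1008 to 3289, 0 to 421, 0 to 195, 0 to 462 and 0 (2103 without orangutan and 2341 without rhesus at the first). With an estimated correlation the adjusted p was 0.187 for pluripotency, 0.325 for neuroepithelium, 0.189 for telencephalon, intermediate progenitors and Cajal-Retzius cells, 0.201 for cortical neurons, midbrain to spinal cord, Nodal targets, glycolysis and lncRNAs, 0.300 for ventral telencephalon and 0.362 for cell cycle and hem; fry gave 0.0518 for hem.

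The ratio of transient shares of lncRNAs to coding genes was 1.21, 0.72, 0.87 and 0.84 when matched on level. By quartile of level, from the lowest up, it was 1.16, 0.71, 0.89 and 0.67, then 1.143, 0.65, 0.87 and 1.33, then 2.37, 1.37, 1.60 and 3.19, and 3.37, 0.70, 1.37 and 4.46 in the highest.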

Other observations

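The genes of the first and second paragraphs below and the tests of feeder RNA, of gene models, of the correlation between lines and of counting noise were chosen after their values or the patterns were seen; the further liver-type genes and the batch question were written down before their values were looked at.

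In rhesus at week 3, the column whose libraries were the most unequal (3.24), a few matrix, pigment and epithelial genes stood high. OGN stood at 1490, COL3A1, a fibrillar collagen, at 8650 (126 at week 0, 805 at week 5), LUM at 3010, TYR, the rate-limiting enzyme of melanin synthesis, at 624 and TP63, a factor of basal epithelium, at 234. Human organoids at week 3 had 2900 for COL3A1, 122 for LUM, 0.675 for TYR and 3.31 for TP63. The 2 rhesus week 5 libraries also differed in cell type markers: in normalized counts PAX6 stood at 3462 and 5954 and HES5 at 239 and 122, while FABP7 stood at 3267 and 3465. In read counts TTR had 1559 and 3928, DLX6-AS1 98 and 272, WNT8B 1961 and 741, COL3A1 580 and 191.

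A few neural and axial genes stood higher at week 0 in the embryonic stem cells than in the induced pluripotent cells. PAX6 stood at 607 in human and 238 in rhesus against 38.7 in chimpanzee and 1.83 in orangutan, GAD1 at 674 and 85.9 against 25.5 and 3.73, and HOXA2 at 66.2 and 37.1 against 0.326 and 0. In orangutan the midbrain-hindbrain genes EN1 (1840 at week 1) and PAX5 (907 at week 2) and the hem gene WNT3A (1100 at week 2) stood above the other lines.

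Genes of fetal liver and yolk sac proteins, most of them secreted, rose in human and rhesus organoids, and most were low at week 5. In human this followed a fall at the step from week 4 to 5, whose libraries carry other codes. The 10 genes noticed were AFP, FGA, FGB, FGG, SERPINA1, APOA1, APOA4, MTTP, PLG and AHSG. At weeks 0, 1, 2, 4 and 5 they summed to 212, 3419, 3568, 2703 and 105 in human and 327, 5425, 4567, 256 and 61.7 in rhesus. The sums were 296, 564, 1424, 288 and 227 in chimpanzee and 2792, 105, 1214, 282 and 122 in orangutan. AFP alone made up most of the week 0 sums in chimpanzee (230) and orangutan (2750). MTTP made up most of the week 2 sums in chimpanzee (1340) and orangutan (1160). APOA1 also rose there, from 18.0 at week 0 to 98.8 at week 3 in chimpanzee and from 18.4 to 53.7 in orangutan. Since the 10 genes were noticed by their rise, 12 further genes of the same tissues were tested. RNA carried over from the feeder layer should let these fall after week 0. From week 0 to 2 the median change of those measured was 1.96 in human (9 of 10 higher) and 2.86 in rhesus (10 of 12 higher). That prediction was written after the rise was seen, and a rise is not what carried-over RNA gives. It therefore adds nothing beyond the rise of the further genes, which the next test uses as well. Cells of that type should raise them, and their median lay at percentile 99.93 of random lists in human and 99.99 in rhesus. It lay at 30.98 in chimpanzee and 55.04 in orangutan. However, APOC1 fell in human (-3.49) and rhesus (-1.55) and AMN did not rise in rhesus (-0.05). Among genes above week 0 at week 5 were TF (49.9 in human, 176 in rhesus), CUBN (390 and 36.2), RBP4 (10.6 in both) and SERPINC1 (25.0 and 9.51). In chimpanzee 5 of 10 and in orangutan 5 of 9 measured further genes were also higher at week 2. These included CUBN (3.60 and 2.29), TF (3.37 and 1.84) and VTN (2.58 and 2.82). APOC1 fell in chimpanzee (-3.89) and orangutan (-3.16) as well. Such cells in both lines from embryonic stem cells remain possible from the list as a whole. The members just named neither point to such cells nor exclude them. Whether the line, the feeder culture, the aggregation or a library batch matters was not tested.

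Genes high in human were listed near 0 at every week of another line. If the projected gene models were the reason, these genes should lack a full model on a placed chromosome: this held for 95.2% of 641 genes in chimpanzee (7.16% of other genes), 84.6% of 565 in orangutan (11.5%) and 85.8% of 492 in rhesus (8.57%). TPT1 was listed at 0 in chimpanzee while its TPM reached 839, PRTG at no more than 1.44 in orangutan with a TPM of 111, and HSP90AA1 at 0 in rhesus with a TPM of 40.03, but such genes with a TPM above 5 numbered only 108 in chimpanzee, 14 in orangutan and 6 in rhesus. Absence of such genes in the count table is therefore likely a property of the models for most of them, and the HES5, MSX1, COL3A1 and XBP1 values near 0 in orangutan and XBP1 values near 0 in rhesus were read with this in mind.

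Human organoids changed more genes from week 4 to 5 (1565) than from week 3 to 4 (630). Counting noise of a shallow library would spare high genes. Of genes at 1000 or more at week 4 or 5, 225 changed, against 78 of the same genes at the step before. Choosing the level on weeks 4 and 5 favours the later step, but counting noise is unlikely to explain changes of such high genes. Of genes at 50 to 200, 785 changed (16.3%, against 3.61% at 1000 or more), so it was not excluded for lower genes. The week 5 libraries of human, and those of rhesus, carry codes outside the run of their line's other weeks, and another batch was expected to switch off steadily expressed genes: 0 genes at 100 or more in weeks 0 to 4 were below 10 at week 5, but 0 were in every line, so reading 0 as evidence against a batch was wrong and the test cannot tell. Continued differentiation of the kind seen elsewhere should correlate with the same step in other lines, where the second highest correlation with human was 0.02004 and the highest between 2 other lines was 0.196; this leaves the question open. Genes below 10 before and at 100 or more at week 5 numbered 11 in human and 0, 1 and 1 elsewhere. Those of human included DLX5, DLX6, HOXA4, PRLHR and the keratins KRT4, KRT5, KRT15 and, with close paralogs, KRT17. Ventral and epithelial genes were thus among them, but so was a HOX gene. Whether they reflect other cells or a batch was not tested.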
